A study of Arabidopsis thaliana with 9 samples.

How the data were processed

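RNA from the vegetative part of Arabidopsis thaliana seedlings was measured on 9 Affymetrix ATH1 arrays, 3 for each of 3 genotypes: wild type Col-0, a line labelled 35S::AVP1 and a line labelled with extra BRI1. Per the labels, all plants were Col-0, were grown in vitro on MS medium at 22 °C with 16 h of light and 8 h of dark, and were harvested at growth stage 1.03; RNA was extracted with the RNeasy kit, and the 3 arrays of a genotype are biological repeats. The genotype entry of the BRI1 line gives BRI1 under its own promoter (pBRI1::BRI1), while its source name gives 35S::BRI1, so the promoter is left open and the line is called the BRI1 line. The design text of the series also speaks of a line overexpressing GRF5, which is not among the 9 arrays and was not analysed here.

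The deposited values are on the log2 scale. Per the submitters' processing notes the authors made them with RMA (background correction, quantile normalization between arrays and summary of the probes of a gene); its version, the probe-to-locus map and the set of arrays normalized together are not given in the sources used here. The deposited table holds 20777 Arabidopsis loci, 1 value per locus and array, and not the vendor's probe sets. The values ran from 2.68 to 14.6, and the array medians from 6.34 to 6.42. Array data give no counts, so the number of arrays limits the precision. The table holds no detection calls. A gene table for the assembly TAIR10.1 was used for names and for the order of genes along chromosomes; 20508 loci were found in it and 269 were not. Symbols are those of that table or of the gene lists described next.

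A linear model with 1 mean per genotype was fitted to all 20777 loci and 9 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with 6 residual degrees of freedom and 3.94 prior degrees of freedom. Each of 3 contrasts (each line against wild type, and the BRI1 line against the arrays labelled 35S::AVP1) was adjusted by Benjamini-Hochberg over all loci, and a locus was called at an adjusted p under 0.05. Its p-values measure the spread between biological repeats. Intervals are 95% intervals from the same model. For AVP1 and BRI1 alone, two-sided exact permutation tests were also run; with 3 arrays against 3 their smallest possible p is 0.1. The replicate numbers were not treated as pairs, since the labels do not say that a number marks a shared batch. Deviations from the group mean correlated at 0.02 to 0.48 in the 9 array pairs that share a number, and at over 0.1 in 5 of them. Pairs from different genotypes with different numbers gave -0.50 to 0.49. Some structure shared by replicate number is therefore possible, and a fit with that number as a block was run as an alternative.

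The 28 gene lists, which hold 459 entries of which 416 were measured, were tested against all other loci with camera (limma, preset correlation 0.01), adjusted over the 28 lists within each contrast. Each was repeated with a correlation estimated per list, and with fry, which asks whether the genes of a list move on balance in one direction and does not compare the list with other genes. Member counts are given at the adjusted p over all loci and adjusted over the list alone. The lists cover brassinosteroid synthesis, signalling and induced genes; cell wall loosening; mitosis, S phase and the endocycle; leaf growth regulators; vacuolar pumps; auxin, gibberellin, cytokinin, salicylic acid and jasmonate; photosynthesis and ribosomes; touch, cold, clock, carbon and phosphate genes; flavonoids and glucosinolates; and markers of stomata, epidermis, meristem, root and flower. AVP1 and BRI1 were left out of the lists of their own pathways.

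Groups, contrasts, thresholds, gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. The rule named AVP1 and BRI1; in each line against wild type, up to 12 loci with the largest rise and 12 with the largest fall among those called with all arrays of one group on one side of the other (5 each way between the lines); up to 4 members with the lowest p of a list that was called or had a called member, and at most 2 of any other list; and up to 10 genes called in both lines. Loci named outside it are marked as chosen after their values were seen. The correlation and covariance of the lines' log2 changes were set against 100 simulated tables with no line effect and a shared wild type mean. The overlap of calls was set only against independent lists, which leave the shared wild type arrays out of account.

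The test was checked on simulated data, in which 200 loci per contrast were given known changes. Of 50 loci changed by 0.5 on the log2 scale it recovered 62%, 82% and 84%. These are for the arrays labelled 35S::AVP1, the BRI1 line and the contrast between them, in that order. Of 50 loci changed by 1 it recovered 98%, 100% and 100%. Among loci given no change it called 6, 10 and 14. The noise was drawn independently for each locus, which real arrays need not follow, so these shares may not carry over to them. The alternatives were quantile normalization or median centring on top of the deposited values, 2 filters on dim loci, fits of only the 2 groups compared, a replicate block, an intensity trend with a robust prior, array weights, unmoderated statistics, stricter thresholds, and leaving out each array in turn. Leaving out wild type replicate 1 and BRI1 line replicate 1 together was added after seeing the data. Alternatives that need probe sets could not be run on a table of loci.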

Results

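Transcript levels were measured on ATH1 arrays in the vegetative part of Arabidopsis seedlings of 3 genotypes, with 3 biological repeats each: wild type, a line labelled 35S::AVP1 and a line with extra BRI1. AVP1 encodes the proton-pumping pyrophosphatase of the vacuole and BRI1 the brassinosteroid receptor, and the series is about leaf enlargement reached in different ways. The deposited values are log2 RMA levels of 20777 loci. Array medians lay between 6.34 and 6.42, and arrays of a genotype correlated across loci at 0.990 to 0.997, where loci are not independent replicates. Wild type arrays correlated with those of the BRI1 line at 0.990 to 0.997, and the arrays labelled 35S::AVP1 correlated with all others at 0.980 to 0.987. The first principal component, which held 55.5% of the variance, placed the 3 arrays labelled 35S::AVP1 at 31.5 to 34.0 and the other 6 at -21.1 to -13.9.

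The first question was whether each line held more RNA of the gene in its label. BRI1 (AT4G39400) rose in the BRI1 line by 2.73 on the log2 scale (SE 0.08, 95% interval 2.57 to 2.90, 6.66-fold; limma adjusted p = 7.75e-08), from 9.55 ± 0.03 in wild type to 12.28 ± 0.09 (SD, n = 3). AVP1 (AT1G15690) did not rise in the arrays labelled 35S::AVP1: its level was 12.54 ± 0.04 against 12.63 ± 0.07 in wild type (SD, n = 3), a log2 change of -0.09 (95% interval -0.25 to 0.07; limma adjusted p = 0.489). AVP1 lay at or above the 99.3 percentile of every array, and where its probes lie relative to the construct is not given in the sources used here; probes outside the construct would check nothing. These arrays are therefore called the arrays labelled 35S::AVP1, and the changes below are not tied to a higher AVP1 level. AVP1 changed by -0.07 in the BRI1 line (adjusted p = 0.985), and BRI1 by 0.20 in the arrays labelled 35S::AVP1 (95% interval 0.03 to 0.37, adjusted p = 0.132). The two-sided exact permutation p was 0.1 for BRI1 in the BRI1 line, the smallest that 3 arrays against 3 allow. In the arrays labelled 35S::AVP1 it was 0.1 for AVP1, which was lower there, and 0.1 for BRI1, which was higher. For AVP1 in the BRI1 line it was 0.3.

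**Figure D1:**
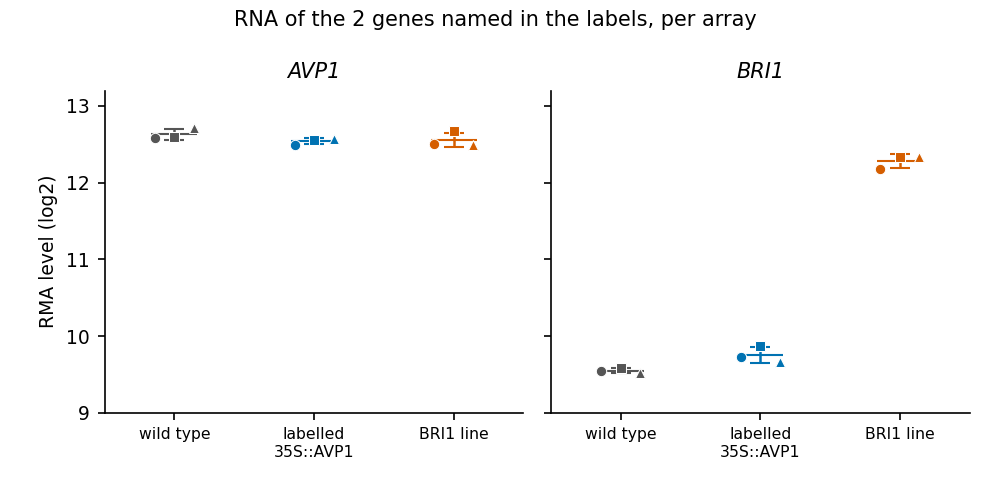
RMA level (log2) of AVP1 and BRI1 on each of the 9 arrays by genotype; points are arrays and lines the group means. BRI1 averages 12.28 in the BRI1 line against 9.55 in wild type, while AVP1 lies between 12.49 and 12.71 on all 9 arrays.

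The arrays labelled 35S::AVP1 were compared with wild type to find the genes that differ in that line. AOP3 (AT4G03050), a dioxygenase that modifies glucosinolate side chains, rose 61.7-fold, from 4.37 ± 0.10 to 10.32 ± 0.20 (SD, n = 3), and HPL1 (AT4G15440), a hydroperoxide lyase of the oxylipin pathway, rose 26.4-fold, from 4.78 ± 0.21 to 9.50 ± 0.25. ECS1 (AT1G31580), which encodes a cell wall protein, fell from 12.88 ± 0.17 to 5.14 ± 0.26, a log2 change of -7.74. AT1G66100 changed by -7.54, and AT2G25450, another dioxygenase of glucosinolate side chains, by -7.31 (limma adjusted p = 4.99e-10 for ECS1 and 6.09e-10 for AOP3). The cysteine-rich receptor-like kinases CRK21 (-5.71) and CRK22 (-3.93) and the downy mildew resistance gene RPP4 (-4.07) were also among the 12 largest falls, with ZW9 (-6.34), AT1G23130 (-5.20), AT1G23960 (-4.75), AT2G01090 (-4.48), AT5G45500 (-4.11) and AT3G60980 (-4.07). The other large rises were AT5G15360 (3.48), AT5G35480 (3.21), AT1G62770 (3.19), AT4G17470 (3.12), AT3G48640 (2.93), AT5G55570 (2.88), the pectin methylesterase ATPMEPCRB (2.82), the endonuclease ENDO5 (2.81), the pathogen response gene LURP1 (2.73) and AT5G26280 (2.7). The 10th percentile of the arrays was 3.71 to 3.79. The line's levels of CRK21 (3.3) and AT2G01090 (3.61) and the wild type levels of AT5G35480 (3.37), AT3G48640 (3.62) and ATPMEPCRB (3.73) lay below or within that range, and there the lower end of the scale limits the fold. ECS1 (5.14) and AT1G23130 (5.93) lay above it in the line, as did AOP3 (4.37) and HPL1 (4.78) in wild type. Without detection calls, background signal may limit the folds of these genes too. Whether the probes match the gene sequences of this line was not tested, so a lower signal need not mean less RNA.

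Of 20777 loci, 2300 (11.1%) differed in the arrays labelled 35S::AVP1 by limma with Benjamini-Hochberg adjustment, 1310 higher and 990 lower. At least 2-fold changes numbered 129 up and 215 down, and at least 4-fold changes 24 up and 60 down. The median log2 change of all loci was 0.05, and the share of called loci that were higher, 57.0%, was 49.2% after quantile normalization and 47.3% after median centring. Levels of the 2 groups did not overlap at 5899 loci (28.4%, against 10% by chance).

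**Figure D2:**
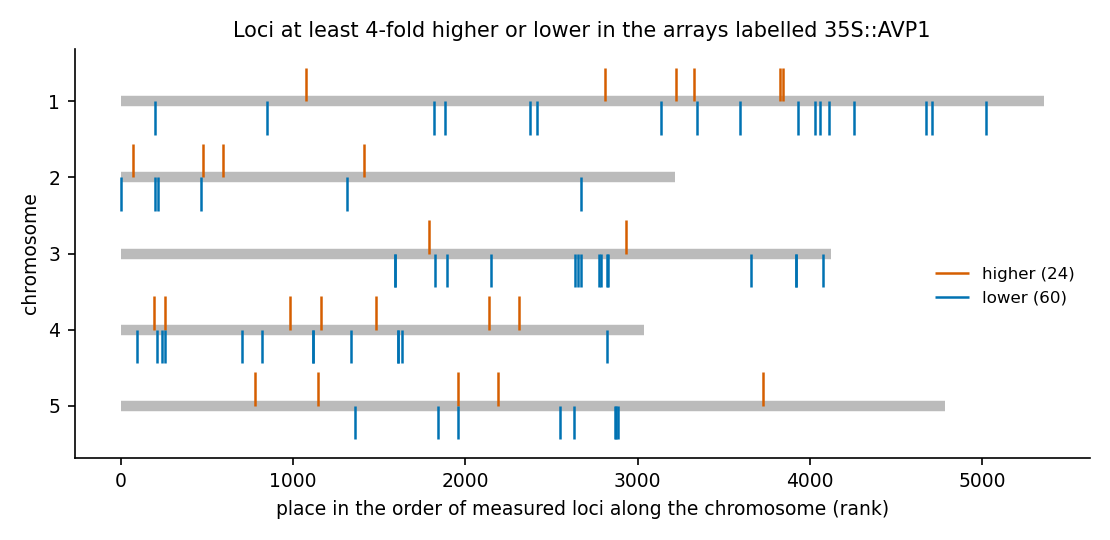
Loci called and at least 4-fold higher or lower in the arrays labelled 35S::AVP1 than in wild type, placed by rank in the order of measured loci (TAIR10.1) along each of the 5 nuclear chromosomes; each tick is 1 locus. The 24 higher and 60 lower loci lie on all 5 chromosomes, 23, 10, 18, 20 and 13 of them on chromosomes 1 to 5.

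Some genes of defence and of hormone pathways were called in the arrays labelled 35S::AVP1, in both directions. Of 19 salicylic acid defence genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them PR2 (1.29), EDS5 (0.68), NIMIN1 (0.42) and WRKY38 (0.36). PR2 was 0.80 without replicate 2 labelled 35S::AVP1. Its call was lost without wild type replicate 1, 2 or 3 or BRI1 line replicate 3 (adjusted p up to 0.0780). The list was higher as a group (median 0.21, camera adjusted p = 0.0107; adjusted p = 0.626 with an estimated correlation), but not without wild type replicate 3 (adjusted p = 0.0785). In the jasmonate list 2 of 17 rose and 3 fell (3 and 3 adjusted over the list alone): AOS, which makes the allene oxide from which jasmonate derives, fell from 9.89 ± 0.18 to 7.93 ± 0.19 (SD, n = 3), and OPR3 changed by -1.11, while CORI3 (1.28) and LOX4 (0.69) rose. Of 9 glucosinolate genes, MYB28 rose (0.72) and MAM1 (-1.04) and CYP83B1 (-0.45) fell. Among hormone genes, IAA17 (0.83), GA20OX1 (0.54) and BIM1 (0.43) rose, and GASA1 (-1.81), IAA4 (-0.78) and the response regulators ARR16 (-1.19) and ARR4 (-0.27) fell. Of 19 auxin genes 1 rose and 1 fell, of 9 gibberellin genes 1 and 1, of 8 cytokinin regulators 0 and 2, and of 12 brassinosteroid signalling genes 1 and 0. Of all loci 11.1% were called, and none of these hormone lists was called as a group. The brassinosteroid synthesis genes BR6OX1 (0.49) and BR6OX2 (0.51) rose and DWF4 fell (-0.34), and of 13 brassinosteroid-induced genes EXPA8 (0.56) and KCS1 (0.39) rose and XTH17 fell (-0.59). Of these calls, ARR4 failed without any 1 of the 9 arrays, and NIMIN1, CYP83B1, GA20OX1, BR6OX1, BR6OX2, DWF4 and KCS1 without some (adjusted p up to 0.132, for BR6OX2). WRKY38 had a wild type level of 3.61, below the 10th percentile of the arrays (3.71 to 3.79), so the lower end of the scale limits its change.

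Of 19 mitotic genes 4 fell and 0 rose in the arrays labelled 35S::AVP1 (5 and 0 adjusted over the list alone): the cytokinesis syntaxin KN (-0.57), CDKB2;1 (-0.51), CYCB1;1 (-0.38) and CYCB1;3 (-0.38). The median of the list was -0.21 and 16 of its members had a negative change (camera adjusted p = 0.000524; adjusted p = 0.626 with an estimated correlation). Of 22 S-phase genes the cyclin gene CYCD3;3 (-0.59), PCNA2 (-0.44) and MCM7 (-0.31) fell and FAS2, a subunit of chromatin assembly factor 1, rose (1.18). The trichome regulators GL2 (-1.2) and GL1 (-0.64) were the 2 of 7 epidermal genes that fell, and that list was lower as a group (median -0.11, adjusted p = 0.0107; adjusted p = 0.626 with an estimated correlation), with a median of -0.07 without wild type replicate 3 (adjusted p = 0.0376). Of 10 stomatal lineage genes 3 fell: SDD1 (-0.58), TMM (-0.43) and SPCH (-0.43). Touch and rapid stress genes had a median change of -0.93, with CAF1A (-1.81) the 1 of 13 that was called (4 fell adjusted over the list alone), and that list was lower as a group (adjusted p = 0.00274; adjusted p = 0.626 with an estimated correlation). Without wild type replicate 1, whose touch genes were high, its median was -0.26 (adjusted p = 0.103), and without wild type replicate 3 it was -1.52. CAF1A was -1.15 and still called without wild type replicate 1. It passed also without wild type replicate 3, and failed without each of the other 7 arrays (adjusted p up to 0.119). CYCB1;1, CYCB1;3, PCNA2, MCM7, SDD1, TMM and SPCH also failed without some arrays (adjusted p up to 0.156, for CYCB1;3).

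Expansins and xyloglucan endotransglucosylases, which loosen cell walls, went both ways in the arrays labelled 35S::AVP1: 7 of 35 rose and 6 fell (9 and 9 adjusted over the list alone), with EXLA1 (1.11) and XTH31 (0.72) up and XTH30 (-0.65) and XTH16 (-0.58) down. Of 31 vacuolar genes 3 rose, namely the exchangers CAX3 (1.53) and NHX2 (0.39) and the soluble pyrophosphatase PPA5 (0.58), and 2 fell, among them the tonoplast aquaporin TIP2;2 (-0.52). TCP2 (-0.93) was the 1 of 24 leaf growth regulators that was called, and it fell. The floral genes SEP3 (1.80) and AG (0.57) and the root-expressed genes PYK10 (0.86) and PHO1 (0.81) rose; the wild type level of AG was 3.39, below the 10th percentile of the arrays (3.71 to 3.79), so the lower end of the scale limits its change. CHI (0.97) rose and FLS1 (-0.35) fell among flavonoid genes, CBF3 (0.82) rose and CBF1 (-0.64) fell among cold genes, and KINB1 (-0.61) fell among sugar-repressed genes. NHX2, TIP2;2, PHO1, FLS1, CBF3 and KINB1 failed without some arrays (adjusted p up to 0.150, for FLS1).

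Of the 28 lists, camera called 4 in the arrays labelled 35S::AVP1: salicylic acid defence up, and mitosis, epidermis and touch down. No call held with an estimated correlation, and only the mitosis list was called when dim loci were removed. The self-contained fry test called salicylic acid defence up (adjusted p = 0.0373), epidermis down and floral and root markers up (0.0180 each), but not mitosis (0.0928) or touch (0.423). Adjusted p-values of the other lists ran upward from 0.0856 for sugar-repressed genes, with 0.0877 for cytokinin regulators and floral markers, 0.160 for leaf growth regulators, 0.165 for stomatal and root lists, 0.257 for ribosomes, 0.307 for phosphate starvation and 0.312 for S phase. They were 0.472 for the brassinosteroid synthesis, gibberellin, glucosinolate and photosynthesis lists, 0.660 for meristem genes, 0.679 for brassinosteroid signalling and the endocycle, 0.706 for jasmonate and flavonoids, 0.819 for cell wall loosening, 0.862 for vacuolar, auxin and cold genes, 0.870 for clock genes and 0.997 for brassinosteroid-induced genes. By limma, 0 members of the clock, endocycle, meristem, phosphate, photosynthesis and ribosome lists were called; at an unadjusted p under 0.05 these lists had 1 of 14, 3 of 12, 0 of 8, 2 of 12, 0 of 22 and 0 of 14. In 9 lists, none of them called, the median, the mean and the test differed in sign.

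The BRI1 line was compared with wild type to find the genes that differ when extra BRI1 is present. Genes of brassinosteroid synthesis fell: BR6OX2, which catalyses the last steps to brassinolide, went from 8.02 ± 0.27 to 6.92 ± 0.13 (SD, n = 3; log2 change -1.10, limma adjusted p = 0.0288), and the cytochrome P450 genes DWF4 from 8.00 ± 0.01 to 7.30 ± 0.13 (-0.70), CPD from 10.68 ± 0.09 to 10.09 ± 0.08 (-0.59) and CYP90D1 from 5.53 ± 0.03 to 5.08 ± 0.06 (-0.45). These 4 of 13 synthesis genes fell and 0 rose (4 and 0 adjusted over the list alone). CPD and CYP90D1 failed without any 1 of the 9 arrays, and BR6OX2 and DWF4 without some (adjusted p up to 0.233, for CPD). The asparaginase gene ASPGA1 (AT5G08100) fell 14.3-fold, from 8.54 ± 0.17 to 4.71 ± 0.14 (SD, n = 3; limma adjusted p = 7.75e-08). PPD2 (AT4G14720), a repressor that limits leaf growth, fell from 7.16 ± 0.16 to 5.92 ± 0.19 (limma adjusted p = 0.00328); its paralog PPD1 was not among the measured loci.

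**Figure D3:**
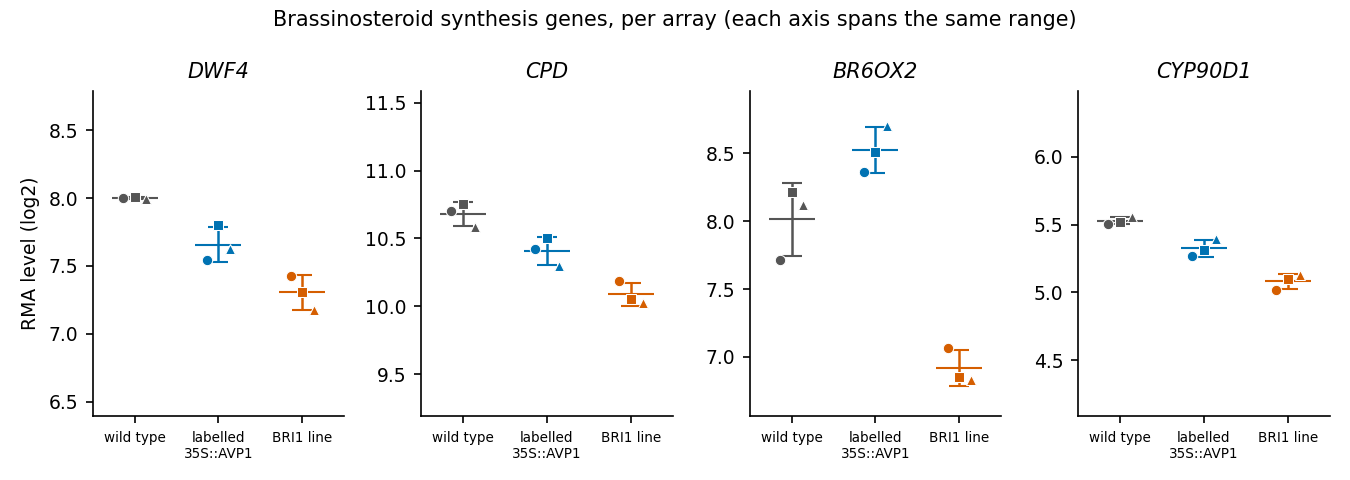
RMA level (log2) of DWF4, CPD, BR6OX2 and CYP90D1 on each array by genotype; points are arrays, lines the group means, and each axis spans the same range. All 4 genes are lower in the 3 arrays of the BRI1 line than in the 3 wild type arrays, and BR6OX2 is highest in the arrays labelled 35S::AVP1, at a mean of 8.52.

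Besides BRI1 the BRI1 line had higher RNA of the floral repressor SMZ (0.98), the transcription factor gene MYB47 (0.61) and AT4G29270 (1.19), AT1G62660 (0.83), AT4G33040 (0.69), AT5G02760 (0.59) and AT1G28570 (0.45). The remaining falls were AT5G26270 (-1.11), the receptor-like kinase gene AT1G72180 (-0.51) and the trypsin inhibitor gene TI2 (-0.43). In all, 17 loci were called, 8 higher and 9 lower, and 1102 had an unadjusted p under 0.05. Quantile normalization gave 9 higher and 5 lower, and median centring 11 and 6. Levels of the 2 groups did not overlap at 2103 loci (10.1%, against 10% by chance), and at all 17 called. The call rested on every array: without wild type replicates 1, 2 and 3 in turn the count was 6, 3 and 9, without replicates 1, 2 and 3 labelled 35S::AVP1 it was 10, 9 and 9, and without those of the BRI1 line 4, 5 and 3. BRI1, ASPGA1 and PPD2 passed in all 9 of these fits and 14 loci failed in some, of which CPD, CYP90D1, AT1G28570, TI2, AT4G33040 and AT5G02760 passed in 0 at an adjusted p under 0.05.

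By gene list, brassinosteroid synthesis was lower in the BRI1 line, with a median of -0.15 (camera adjusted p = 3.04e-07; adjusted p = 0.0410 with an estimated correlation, and 1.43e-05 at most without any 1 array). Genes known to be induced by brassinosteroid were higher as a group (median 0.19, 9 positive and 4 negative, camera adjusted p = 0.000326), but not with an estimated correlation (adjusted p = 0.377). Limma called 0 of 13 over all loci, 5 adjusted over the list alone and 6 at an unadjusted p under 0.05. The positive values included XTH19 (1.39), BEE1 (0.64), SAUR15 (0.52) and EXPA8 (0.40). Among the negative was TCH4, at 7.13 to 8.13 in the BRI1 line and 7.34 to 10.67 in wild type. Without BRI1 line replicate 1 that list gave adjusted p = 0.0616. Of 12 brassinosteroid signalling genes 0 were called by limma, 2 at an unadjusted p under 0.05: the inactivating enzyme gene BAS1 (0.85, adjusted p = 0.121) and BEH2 (-0.42, adjusted p = 0.0626).

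Flavonoid genes were higher as a group in the BRI1 line (median 0.33, 11 of 12 positive; camera adjusted p = 6.36e-08; adjusted p = 0.285 with an estimated correlation), with 0 called by limma over all loci, 4 adjusted over the list alone and 6 at an unadjusted p under 0.05. Without wild type replicate 3 its median was 0.15 (adjusted p = 0.000192). Its values included DFR (1.30), the glycosyltransferase gene UF3GT (0.99) and the anthocyanin regulator PAP1 (0.92). The glucosinolate list was higher (median 0.23, 9 of 9 positive; adjusted p = 0.000431; adjusted p = 0.431 with an estimated correlation), but not without wild type replicate 3 (median 0.06, adjusted p = 0.127) or BRI1 line replicate 1 (median 0.13, adjusted p = 0.130). Its median was 0.15 without BRI1 line replicate 3, 0.39 without wild type replicate 1 and 0.43 without BRI1 line replicate 2. Auxin genes (median 0.09, adjusted p = 0.00823; adjusted p = 0.377 with an estimated correlation) were higher too, but not without wild type replicate 3 (median 0.05, adjusted p = 0.191) or BRI1 line replicate 1 (median 0.02, adjusted p = 0.427), and their median was 0.15 without wild type replicate 2. Gibberellin genes, with GA3OX1 at 0.77, had adjusted p = 0.0491 (median 0.12; adjusted p = 0.357 with an estimated correlation), and the call was lost without any array but replicate 2 labelled 35S::AVP1 (up to adjusted p = 0.123), and after quantile normalization (adjusted p = 0.0671) and median centring (adjusted p = 0.0553). Root-expressed genes, with PYK10 at 0.68, had adjusted p = 0.0227 (median 0.07; adjusted p = 0.285 with an estimated correlation), lost after quantile normalization (adjusted p = 0.0638) and without wild type replicate 2 (median 0.04, adjusted p = 0.124) or BRI1 line replicate 1 (median 0.11, adjusted p = 0.0616), and with a median of 0.03 without BRI1 line replicate 2.

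Cell cycle lists were lower in the BRI1 line by small amounts. Mitotic genes had a median of -0.11, with 17 of 19 negative (camera adjusted p = 0.000625; adjusted p = 0.413 with an estimated correlation), and S-phase genes of -0.13, with 16 of 22 negative (adjusted p = 0.00146; adjusted p = 0.377 with an estimated correlation). Limma called 0 members over all loci in each, 3 at an unadjusted p under 0.05, and CDC6 (-0.60) alone adjusted over the list alone. Sugar-repressed genes were lower (median -0.28, SEN1 -0.96; adjusted p = 0.00168; adjusted p = 0.377 with an estimated correlation), as were touch genes (median -1.10, 12 of 13 negative; adjusted p = 3.04e-07; adjusted p = 0.377 with an estimated correlation). Touch genes were high in wild type replicate 1, and without it the touch list had a median of -0.45 (adjusted p = 0.00402; -1.74 without wild type replicate 3), the sugar-repressed list a median of -0.18 (adjusted p = 0.385) and the mitotic list of -0.05 (adjusted p = 0.123). The mitotic median was -0.17 without wild type replicate 3 and -0.07 without BRI1 line replicate 2. The S-phase call was lost without wild type replicate 2 (median -0.03, adjusted p = 0.194), and its median was -0.08 without wild type replicate 3.

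Camera called 11 of 28 lists in the BRI1 line, 6 up and 5 down, 1 of them with an estimated correlation; fry called brassinosteroid synthesis alone (adjusted p = 0.00212). PPD2 was the 1 of 24 leaf growth regulators that was called, and that list gave adjusted p = 0.494. Cell wall genes gave adjusted p = 0.165, with 0 called by limma, 6 higher and 2 lower adjusted over the list alone and 9 at an unadjusted p under 0.05, among them XTH31 (0.54) and EXLA1 (-0.77). Adjusted p was 0.550 for vacuolar genes and brassinosteroid signalling, 0.436 for jasmonate and 0.972 for salicylic acid defence and for clock genes. In 6 lists, none of them called, the median, the mean and the test differed in sign.

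The contrast of the BRI1 line with the arrays labelled 35S::AVP1 asked where the lines differ from each other. Most of its largest differences were at loci that set the arrays labelled 35S::AVP1 apart from wild type: ECS1 was higher in the BRI1 line by 7.91 on the log2 scale (SE 0.13, n = 3; limma adjusted p = 4.02e-10), AT2G25450 and AT1G66100 by 7.42, ZW9 by 6.72 and CRK21 by 5.69, and AOP3 (-5.81), HPL1 (-4.68), AT5G15360 (-3.61) and AT5G35480 (-3.32) were lower. The lower end of the scale limits the difference of CRK21, at 3.3 in the arrays labelled 35S::AVP1, and of AT5G35480, at 3.25 in the BRI1 line. ASPGA1 (-3.90), the third largest of the lower loci, was not called in the arrays labelled 35S::AVP1 against wild type (0.07), and BRI1 was higher (2.53, adjusted p = 1.74e-08). The brassinosteroid synthesis genes separated the lines: BR6OX2 differed by -1.61 (adjusted p = 4.97e-05), BR6OX1 by -0.61, DWF4 by -0.35, CPD by -0.32, and 5 of 13 were lower and 0 higher in the BRI1 line. DWF4 and CPD failed without some arrays (adjusted p up to 0.120, for CPD). PPD2 differed by -0.98 and TCP2 by 0.91.

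Some genes of defence and secondary metabolism differed between the lines as well, while most members of these lists were not called. Relative to the arrays labelled 35S::AVP1, 6 of 19 salicylic acid defence genes were lower in the BRI1 line and 0 higher (9 and 1 adjusted over the list alone), among them PBS3 (-1.12) and EDS5 (-0.56). PBS3 was -0.71 without replicate 2 labelled 35S::AVP1, and its call was lost without BRI1 line replicate 1, 2 or 3 (adjusted p up to 0.0866). EDS5 was lost without any 1 array of either line (adjusted p up to 0.0862). AOS (2.11) and OPR3 (1.44) of jasmonate synthesis were higher and CORI3 (-1.18) lower. Of 9 glucosinolate genes 3 were higher, among them MAM1 (1.2) and CYP83B1 (0.67), and 1 was lower. PAP1 (0.98) and FLS1 (0.45) were higher and CHI (-0.70) lower among flavonoid genes. Of 13 brassinosteroid-induced genes 3 were higher in the BRI1 line, XTH19 (1.31) among them, and 2 lower, including PRE1 (-1.11). Higher were 2 of 8 cytokinin regulators (ARR16, 1.51), 3 of 9 gibberellin genes (GASA1, 0.93) and 3 of 7 epidermal genes (GL2, 0.94), with 0 lower. Of 10 stomatal genes 2 were higher (TMM, 0.48) and 1 lower. Lower were 2 of 6 floral genes (SEP3, -2.27) and 1 of 31 vacuolar genes (CAX3, -1.90), with 0 higher. Of 35 cell wall genes 7 were higher and 5 lower (EXLA1, -1.89). FLS1, XTH19, PRE1, GASA1 and TMM failed without some arrays (adjusted p up to 0.0886, for PRE1).

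Between the lines 2144 loci differed (limma, Benjamini-Hochberg), 841 higher and 1303 lower in the BRI1 line; quantile normalization gave 1044 and 950, and median centring 1069 and 825, so which direction was more frequent changed with the scaling. Groups did not overlap at 6303 loci (30.3%, against 10% by chance). Without BRI1 line replicate 3 the count was 1298, and with other arrays left out 1435 to 2419.

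Camera called 10 of 28 lists between the lines, and none of these calls held with an estimated correlation or after removal of dim loci. Fry called brassinosteroid synthesis (adjusted p = 0.00224), brassinosteroid signalling (0.0135), epidermal (0.0141), floral and gibberellin (0.01 each) and salicylic acid defence lists (0.0178). Higher in the BRI1 line were the flavonoid list (median 0.39, adjusted p = 0.00174; adjusted p = 0.456 with an estimated correlation), the glucosinolate list (0.32, adjusted p = 0.0120; adjusted p = 0.620 with an estimated correlation) and the epidermal list (0.11, adjusted p = 0.0120; adjusted p = 0.388 with an estimated correlation). The stomatal list (0.14, adjusted p = 0.0241; adjusted p = 0.456 with an estimated correlation), the gibberellin list (0.05, adjusted p = 0.0346; adjusted p = 0.388 with an estimated correlation) and the mitotic list (0.09, adjusted p = 0.0367; adjusted p = 0.620 with an estimated correlation) were higher too. So were brassinosteroid-induced genes (0.18, adjusted p = 0.0420; adjusted p = 0.618 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0870) or median centring (adjusted p = 0.10). Lower were salicylic acid defence (-0.29, adjusted p = 0.0120; adjusted p = 0.456 with an estimated correlation), brassinosteroid synthesis (-0.14, adjusted p = 0.0346; adjusted p = 0.388 with an estimated correlation) and floral genes (-0.18, adjusted p = 0.0442; adjusted p = 0.557 with an estimated correlation). In 9 lists, none of them called, the median, the mean and the test differed in sign.

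Several of these calls rested on single arrays. The glucosinolate median was 0.51 without BRI1 line replicate 2, and the gibberellin median ran from 0.0024 without replicate 1 labelled 35S::AVP1 to 0.16 without BRI1 line replicate 1. Without BRI1 line replicate 1 the glucosinolate and stomatal lists each gave adjusted p = 0.0747, the mitotic list 0.103 and brassinosteroid-induced genes 0.243. The mitotic list was also lost without replicate 2 labelled 35S::AVP1 (median 0.06, adjusted p = 0.154) and BRI1 line replicate 3 (adjusted p = 0.117), and the gibberellin list without BRI1 line replicate 3 (adjusted p = 0.0559). Without replicate 3 labelled 35S::AVP1, brassinosteroid synthesis gave adjusted p = 0.0660 and brassinosteroid-induced genes 0.219; without BRI1 line replicate 2, brassinosteroid synthesis gave 0.0516. Floral genes were lost without any of the 3 wild type arrays (adjusted p = 0.0647, 0.0515 and 0.0534), replicate 1 labelled 35S::AVP1 (0.103), and BRI1 line replicates 1 (0.0955) and 3 (0.0638).

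Both lines were set side by side to find genes that moved in each. Of the 17 loci called in the BRI1 line, 8 were also called in the arrays labelled 35S::AVP1. Higher in both were MYB47 (1.14 in the arrays labelled 35S::AVP1 and 0.61 in the BRI1 line), AT5G02760 (0.45 and 0.59), AT1G62660 (0.43 and 0.83) and AT4G33040 (0.83 and 0.69). Lower in both were AT5G26270 (-2.06 and -1.11), DWF4 (-0.34 and -0.70) and TI2 (-0.24 and -0.43), while BR6OX2 went in opposite directions (0.51 and -1.10). In the arrays labelled 35S::AVP1 the calls of AT1G62660, DWF4, TI2 and BR6OX2 failed without some arrays (adjusted p up to 0.132, for BR6OX2). Independent lists would share 0.504 loci up and 0.429 down, against the 4 and 3 counted, but both lines were compared with the same 3 wild type arrays, which alone make loci coincide. Across loci the log2 changes of the lines correlated at 0.275, and 100 simulated tables with no line effect gave 0.498 on average. The covariance of the lines' changes was 0.0141 against 0.00670 simulated. The 2 correlations are not comparable, since large changes in 1 line alone lower a correlation and the simulated tables hold none. The lower value therefore does not show less agreement than the shared arrays give. Whether the covariance differs beyond chance was not tested.

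**Figure D4:**
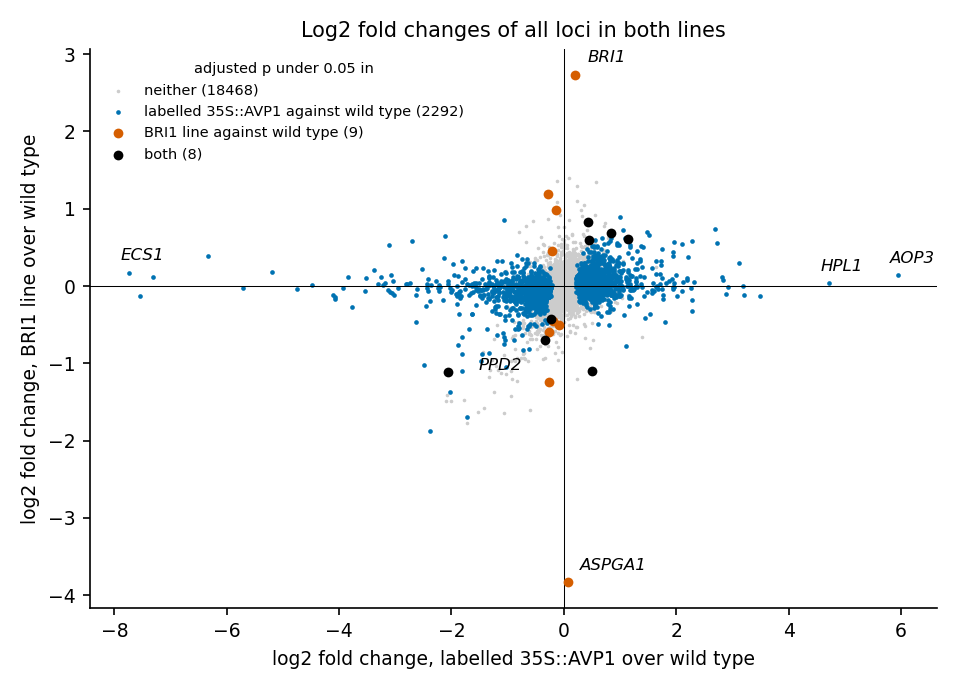
Log2 fold change over wild type of each of the 20777 loci in the arrays labelled 35S::AVP1 (x axis) and in the BRI1 line (y axis), coloured by the comparison in which the locus was called. Loci called in the arrays labelled 35S::AVP1 spread along the x axis from ECS1 at -7.74 to AOP3 at 5.95, while BRI1 (2.73) and ASPGA1 (-3.84) lie far along the y axis.

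Arrays of a genotype differed in clock and touch genes. CCA1, a morning-phased clock gene, ranged over the 9 arrays from 4.88 to 8.09, and the evening-phased genes TOC1 and ELF4 from 7.48 to 9.46 and from 6.57 to 9.37. CCA1 was highest in replicate 1 of each genotype. Touch genes were highest in wild type replicate 1, with ZAT10 at 8.41, TCH4 at 10.67 and WRKY40 at 7.31; the median of the touch list, relative to the wild type mean of each gene, was 1.31 in that array, -0.09 and -1.19 in wild type replicates 2 and 3, and -1.29 to -0.64 in the arrays of the lines. With the replicate number as a block, limma called 2602 loci in the arrays labelled 35S::AVP1 (1520 higher, 1082 lower), 23 in the BRI1 line (11 and 12) and 2382 between the lines (928 and 1454).

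**Figure D5:**
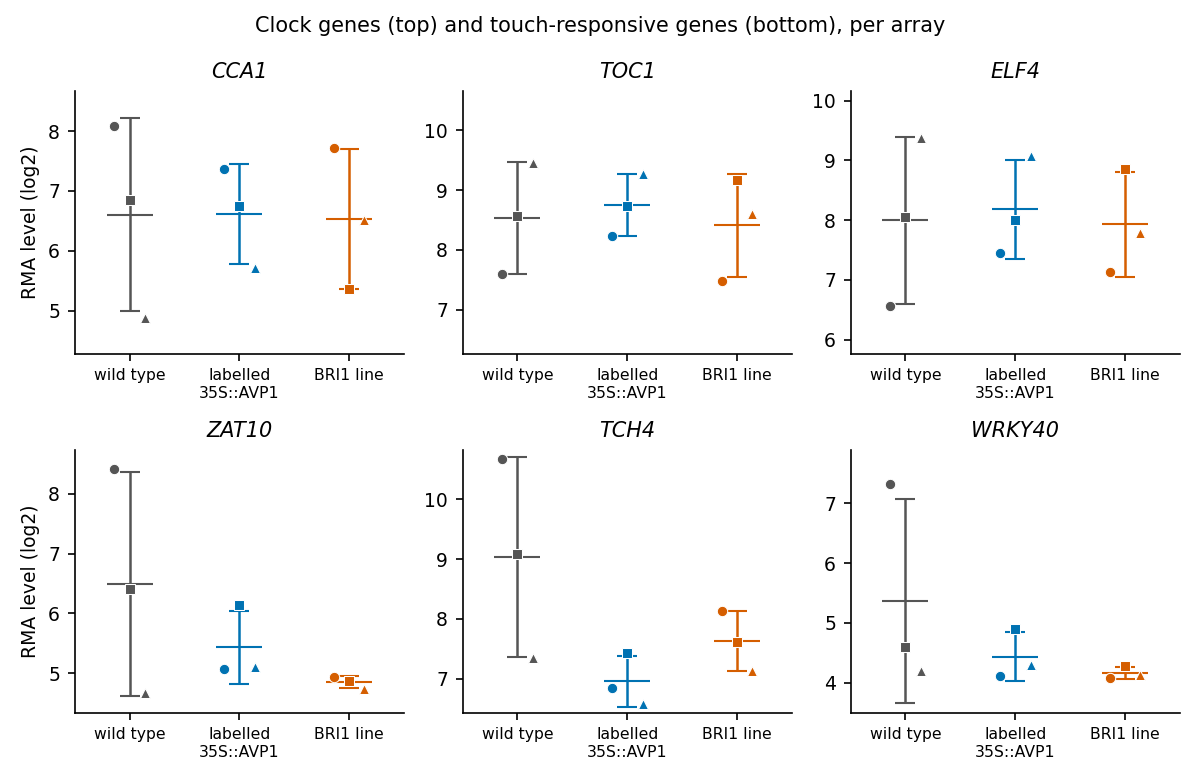
RMA level (log2) of the clock genes CCA1, TOC1 and ELF4 and of the touch-responsive genes ZAT10, TCH4 and WRKY40 on each array by genotype; points are arrays, lines the group means, and each axis spans the same range. Wild type replicate 1 holds the highest CCA1 (8.09) and the highest ZAT10 (8.41), TCH4 (10.67) and WRKY40 (7.31).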

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

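The alternative that left out wild type replicate 1 and BRI1 line replicate 1 together was chosen after seeing the data; all others were planned. AVP1 in the arrays labelled 35S::AVP1 and BRI1 in the BRI1 line kept their direction and their side of the threshold under every alternative run (-0.11 to -0.05 and 2.71 to 2.79 without 1 array). The count for the BRI1 line against wild type, 17, was 7 with only those groups fitted, 28 with array weights, 2 without moderation, 3 at an adjusted p under 0.01 and 5 in the alternative chosen after seeing the data; all 17 were among the 28, and the cause was not tested. Without 1 array the counts were 1568 to 2161 for the arrays labelled 35S::AVP1, 3 to 10 for the BRI1 line and 1298 to 2419 between them; the cause was not tested. Stricter thresholds left 912 (1.5-fold) and 1156 (adjusted p under 0.01) of 2300 loci, and 845 and 1051 of 2144. With the replicate block the counts were 2602, 23 and 2382, of which 2195, 12 and 2009 loci were also called without it. The correlation of the lines' changes, 0.275, was 0.23 to 0.40 without 1 array.

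Called lists, 4, 11 and 10 in the 3 contrasts, numbered 3 to 7, 6 to 12 and 5 to 10 without 1 array. Either filter on dim loci left 1 in the arrays labelled 35S::AVP1 and 0 between the lines (camera, adjusted p under 0.05). An estimated correlation left 0, 1 and 0; fry called 1 in the BRI1 line and 6 between the lines, and the alternative chosen after seeing the data 6 and 4. The cause was not tested.

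Of the values of named genes under alternatives, 2186, 1538 and 1856 kept their direction and side of the threshold in the 3 contrasts, 185, 155 and 177 no longer passed and 47, 17 and 38 newly passed. Those that turned sign had not passed. PI between the lines was 0.015 after quantile normalization, 0.024 after centring and -0.070 to 0.022 without 1 array, above 0 without replicate 1 labelled 35S::AVP1 (0.0068) or BRI1 line replicate 3 (0.022). AVP1 between the lines was -0.037 to 0.049, below 0 without BRI1 line replicate 2 (-0.037) or replicate 1 labelled 35S::AVP1 (-0.0039). ARR9 in the arrays labelled 35S::AVP1 was -0.73 to 0.017, above 0 without wild type replicate 1, also in the alternative chosen after seeing the data (0.017). EDS5 in the BRI1 line was -0.059 to 0.21, below 0 without wild type replicate 2. LFY in the BRI1 line was -0.13 to 0.0073, above 0 without BRI1 line replicate 1 and in the alternative chosen after seeing the data (0.0026). Between the lines RVE1 was -0.030 to 0.83 and ARR9 -0.026 to 0.47, both below 0 without BRI1 line replicate 1 and in the alternative chosen after seeing the data (-0.030 and -0.026). The cause was not tested. Alternatives that need probe sets (removing cross-hybridising ones, or averaging those of a gene) were not run, since the table holds loci. The lower end of the scale limits the falls of CRK21 and AT2G01090 in the arrays labelled 35S::AVP1, whose levels of 3.3 and 3.61 lie below the 10th percentile of the arrays (3.71 to 3.79).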

Other observations

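Among the tests of this part, those on the origin of the differences in the arrays labelled 35S::AVP1, on the neighbours of ASPGA1 and on clock and touch genes were chosen only after the result was seen; the splits of the arrays and the test on root genes were planned. Disease resistance genes of the NB-LRR class, gathered after RPP4 had been seen among the largest falls, differed in the arrays labelled 35S::AVP1: 15 of 25 measured were called by limma, 10 of them at least 2-fold lower, and those that rose, WRR4 (0.59) and SUMM2 (0.55), rose by less than 2-fold. RPP13 changed by -3.77, RPP2A by -3.53, SNC1 by -3.26, CSA1 by -3.10 and the adjacent pair RPS4 and RRS1 by -3.04 and -2.02. RLM3 (-1.91), CHS3 (-1.63) and RPP2B (-1.03) were lower as well, while RPM1 (0.07) did not pass. In the BRI1 line limma called 0 of the 25, with 1 at an unadjusted p under 0.05, and RPP4 stood at -0.16 there; 13 of the 25 were called between the lines.

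Some genes known to differ between natural accessions of Arabidopsis were also called in the arrays labelled 35S::AVP1, where 11.1% of all loci were called. They were likewise chosen after AOP3 had been seen, and were not tested as a set against other loci. AOP3, HPL1 (4.72) and MAM1 (-1.04), named above, are among them. AOP2, the neighbour of AOP3 with which it shares the side-chain step of glucosinolate synthesis, changed by -3.38, opposite to AOP3. The epithiospecifier gene ESP rose by 0.69 (adjusted p = 0.00167), and FLC, a repressor of flowering, by 0.89 (adjusted p = 0.00173).

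Of 73 chloroplast loci 5 were higher and 7 lower in the arrays labelled 35S::AVP1, and of 31 mitochondrial loci 3 and 1. Between the lines 7 and 6 chloroplast loci and 1 and 4 mitochondrial loci differed.

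The arrays labelled 35S::AVP1 differed from wild type at many loci, some by over 16-fold, while AVP1 RNA did not rise. A swap with the BRI1 line is excluded, since BRI1 changed by only 0.20 in these arrays and by 2.73 in the BRI1 line. No chromosome held more than 27.4% of the 84 loci that changed at least 4-fold. Their spread argues against 1 segment of another genome around an insertion holding most of these loci. A segment that changes genes elsewhere was not tested and stays open. Another genetic background of this line is a candidate explanation: among the 19 resistance genes not seen before the test 4 (21.1%) were called and at least 2-fold changed, against 1.61% of other loci (Fisher's exact p = 0.00022). It stays open, since those genes neighbour ones already seen and the labels give Col-0. The 84 loci fell in 60 of 208 blocks of 100 neighbouring loci, fewer than the median of 69 in random draws (share 0.0018 of 10000). The draws place loci singly, while changed loci such as AOP3 and AOP2 or CRK21 and CRK22 are adjacent, so the block count cannot decide. With another background, probes may not match the line's sequence, and a lower signal need not be less RNA. Expression of the 35S::AVP1 construct stays open as well, since AVP1 changed by -0.092 but the place of its probes is unknown.

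ASPGA1 fell by 3.84 on the log2 scale in the BRI1 line. Of its 10 nearest measured neighbours in gene order (TAIR10.1), 0 were called by limma (2 at an unadjusted p under 0.05). The largest of their changes was 0.267 in size and their lowest adjusted p was 0.771. These values argue against a fall of similar size over a longer stretch, for neighbours bright enough to show one. BIM1, 1 of them, lay at 7.84 to 7.97 in wild type. A smaller change, or one that spares or falls short of these neighbours, stays open. A change at ASPGA1 itself, in the line's DNA or through extra BRI1, was not tested.

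Within genotypes, 1 axis held 45.4% of the variance and ran from wild type replicate 1 (-23.5) to wild type replicate 3 (20.7). Whether clock or touch genes follow that axis was not tested. Harvest at different times of day may account for part of the spread within genotypes. Of 14 clock genes, 11 lay among the 5% of loci with the largest such spread, against 4.95% of other loci (one-sided Fisher's exact p = 1.47e-12). Different handling at harvest may account for another part, since all 13 touch genes did (one-sided Fisher's exact p = 1.14e-17). Fisher's test counts genes as independent, while the touch genes moved together (estimated correlation 0.810 in the list tests). The p-values for these lists therefore do not measure the spread between arrays and overstate the evidence. Wild type replicate 1 holds the highest CCA1 and the highest ZAT10, while in the BRI1 line CCA1 ranged from 5.37 to 7.72 and the touch median only from -1.23 to -1.09. How much each contributes was not tested. Different shares of root tissue stay open: 1 of 14 root-expressed genes did (7.14% against 5.0%, one-sided Fisher's exact p = 0.512), a result set in advance to count against them. That bound was wrong, since a p above 0.05 over 14 genes, 4 of them below the lower quartile of levels, excludes nothing. No biological explanation was tested.

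Other splits of the same arrays into 3 and 3 were fitted in the same way for each contrast, and the 10 splits are too few for a share under 0.05, with 1 of 10 splits, the real one, reaching the real count each time. The real split called 2300 loci for the arrays labelled 35S::AVP1 and the highest other split 0; the figures were 17 and 1 for the BRI1 line against wild type, and 2144 and 0 between the lines.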
